A study of Arabidopsis thaliana with 12 samples.

How the data were processed

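RNA sequencing counts of 12 Arabidopsis thaliana seedling libraries were analysed, 3 in each of 4 groups. Per the labels' protocols, messenger RNA libraries were made from 5 µg of RNA with the NEBNext kit. The strand of the reads is not given in the sources used here. Per the submitters' processing notes, FastQC, Bowtie 0.12.8, SAMtools 0.1.18 and the TAIR10 genome were used. The role and settings of each tool, the read counter and the handling of reads with several hits are not given in the sources used here. The deposited files hold raw counts per gene, 1 library per file, for 28775 genes. Their values are whole numbers with a different total in each file, and 0 library columns were left unmatched to a sample.

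Gene names, products and exon overlaps came from the TAIR10.1 annotation, to which 28009 of the 28775 genes matched by locus code. Because that release differs in name from the one in the processing notes, no coordinates are printed. In it 6766 genes share exon sequence with another gene. In 1288 genes at least 20% of the distinct 50-base stretches of the longest transcript also occur in another gene. Reads from overlapping genes cannot be told apart without the strand. Of 19208 genes with at least 50 counts, 128 had counts equal to those of another gene in every library.

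Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 18388, and libraries were scaled by the trimmed mean of M values (TMM). All 12 libraries entered 1 quasi-likelihood fit with group as the only term, with a common biological coefficient of variation of 13.2%. The contrasts were each line against its own wild type, the difference between these 2 responses, and the wild type with 6 d of Est against that with 1 d. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Calls shared by the lines were compared with Fisher's exact test, two-sided, adjusted over 4 overlaps. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

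Before the data were examined, 26 gene lists were fixed by locus code. They were SnRK1 subunits, C and S1 bZIPs, branched-chain amino acid breakdown, other amino acid breakdown, dark-induced and SnRK1 marker genes, trehalose metabolism, autophagy, fatty acid beta-oxidation and glyoxylate cycle, starch breakdown, light harvesting and photosystems, Rubisco small subunits and activase, cytosolic ribosomal proteins, and senescence and chlorophyll breakdown. The others were salicylic acid and immune response, jasmonate response, abscisic acid and drought or cold response, circadian clock, heat shock proteins, anthocyanin and flavonoid synthesis, glucosinolate synthesis, nitrate and ammonium assimilation, alternative respiration, cell division, root markers, flower markers and seed storage markers. The last 3 and cell division served as checks of tissue make-up. The 24 lists with at least 3 members tested were compared with other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. fry tested whether the genes of a list move, on balance, one way, and does not compare them with other genes. Adjusted p-values of lists are over the lists of a comparison. The glucosinolate gene AOP2 is not in the table analysed here.

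The genes named were set by a rule fixed before the data were examined. It takes the targeted genes, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and every library of 1 group beyond every library of the other, and the 4 members with the smallest p of each list that camera called or that had at least 3 called members. It adds the 10 genes called in the same direction in both lines with the smallest larger p, up to 5 called in opposite directions, and the 5 highest and 5 lowest of the difference. Genes outside it are named only as members of a list or as targeted genes seen in another comparison. A fold against a group at 0 counts is a lower bound against a floor of 3 counts over the group. These floors and the intervals of count ratios cover counting error only. Standard errors of log2 fold changes were derived from the F statistic of the quasi-likelihood test. The 95% intervals of log2 fold changes use them, so they draw on the spread between libraries. They take the residual degrees of freedom of the design alone, which differ from those of the test. The intervals can therefore disagree with its p-values, and may be too narrow for genes with few counts.

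Alternatives fixed before the data were examined were size factors by relative log expression, library totals alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, at least 5 CPM in at least 3 libraries, only the groups compared in the fit, a replicate block, each library left out in turn, organelle genes left out, and a change of at least 2-fold. After seeing the data 4 more were added: overlapping or identically counted genes left out, counts thinned to the smallest library, the S1-labelled line against all 6 wild-type libraries, and scaling on the 5000 most expressed genes. A comparison of gene families named by the annotation was also chosen after seeing the data, and its rule for reading family names was corrected for cytochrome P450 after a first result, which moved that family from 11 of 113 to 12 of 117 genes.

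The test was checked on simulated counts with 200 genes changed, at the depth of each library. In the SnRK1 comparison it called 29.9%, 64.2% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, and in the S1 comparison 16.4%, 64.2% and 90.9%. For the difference these were 4.48%, 40.3% and 83.3%, and for the wild types 29.9%, 68.7% and 97.0%. Of the genes called, 9.22%, 8.06%, 6.59% and 6.47% were unchanged ones in the 4 comparisons. In these runs 141, 124, 91 and 139 genes were called in the SnRK1, S1, difference and wild-type comparisons. The real data gave 12582, 474, 10015 and 2227. An adjusted p under 0.05 is less strict where more genes are called. The simulated shares therefore do not carry over to the real comparisons, least of all to the SnRK1 comparison and the difference.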

Results

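RNA from seedlings of Arabidopsis thaliana (ecotype Col-0) was sequenced as 12 libraries in 4 groups of 3. The series asked which genes that respond to starvation in short-term darkness depend on SnRK1, an energy-sensing protein kinase, and on the S1 group of bZIP transcription factors. One line combined a knockout of the first SnRK1 catalytic subunit with an inducible knockdown of the second. The other combined knockouts of bZIP1 and bZIP53 with an inducible knockdown of bZIP2, bZIP11 and bZIP44. Each line had its own wild type. The SnRK1 line and its wild type received the additive named Est in the labels for 6 d from an age of 14 d. The S1 line and its wild type grew 5 d longer without it and then received it for 1 d. All plants were 3 weeks old and were harvested together after the night had been prolonged by 6 h. No library came from plants without the prolonged night or without Est, so the response to darkness itself is not measured here.

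Library totals were 9403687, 7204258 and 3760168 counts in the wild type of the SnRK1 experiment and 6548064, 8047343 and 5079680 in the SnRK1 line. In the S1 experiment they were 7762138, 4721350 and 5563168 in the wild type and 8598928, 5421722 and 6794219 in the S1 line. Of 28775 genes listed, 18388 had enough counts to be tested. Expression levels are given as normalised CPM, mean ± SD of n = 3, and log2 fold changes with their standard error. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within a group, log CPM values of 2 libraries correlated across genes at r = 0.970 to 0.986, and every pair differed by more than counting noise (chi-square per gene 2.80 to 19.2).

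The first principal component of log CPM held 79.0% of the variance and parted the SnRK1 line, at 132 to 167, from the other 9 libraries, at -59.1 to -33.5. The second held 6.0%. The share of counts in the 10 most abundant genes of a library was 4.1% to 5.27% in the SnRK1 line and 10.8% to 12.3% in its wild type.

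**Figure D1:**
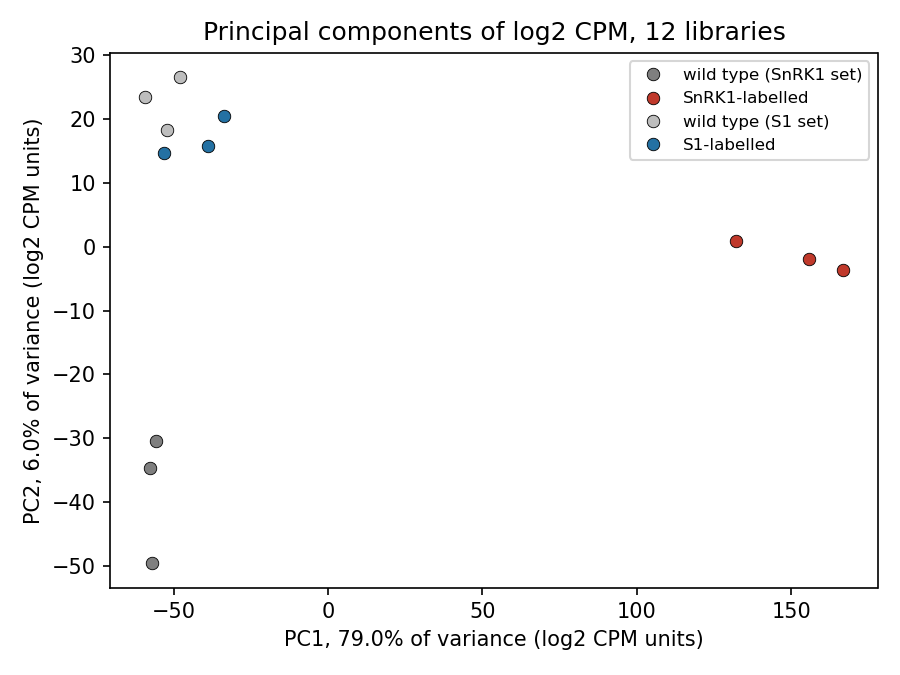
Principal components 1 (79.0% of the variance) and 2 (6.0%) of log CPM over all tested genes, 1 point per library, coloured by group. The 3 SnRK1 libraries lie at 132 to 167 on the first component and the other 9 between -59.1 and -33.5.

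The targeted genes were examined first. KIN10 (AT3G01090), the catalytic subunit knocked out in the SnRK1 line, still gave reads: 61.6, 65.6 and 60.2 CPM in its 3 libraries and 86.2, 99.6 and 78.5 in the wild type. Its log2 fold change was -0.50 ± 0.12 (adjusted p = 0.00112), but 0.10 (adjusted p = 0.436) when libraries were scaled by their totals alone. Over the 25 other settings tried its adjusted p ran from 0.000544 to 0.436. KIN11 (AT3G29160), the subunit under inducible knockdown, was at 28.3, 29 and 43.4 CPM against 98.4, 114 and 85.4 (log2 fold change -1.58 ± 0.16, adjusted p = 1.86e-07).

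In the S1 line bZIP1 (AT5G49450) was at 17.9, 20.4 and 26.6 CPM against 135, 143 and 119 in its wild type (log2 fold change -2.62 ± 0.18, adjusted p = 3.00e-07). The gene bZIP53 (AT3G62420) was at 15.1, 17.8 and 16.7 CPM against 71.9, 75.4 and 89.5 (-2.26 ± 0.13, adjusted p = 7.06e-08). The gene bZIP2 (AT2G18160), listed as knocked down, was not lower: 58.8, 72.2 and 68.9 CPM against 62.5, 74.4 and 61.4 (0.01 ± 0.12, adjusted p = 0.979). For bZIP11 (AT4G34590) the level went from 1.42 ± 0.332 to 1.18 ± 0.470 CPM (-0.20 ± 0.34, adjusted p = 0.872). For bZIP44 (AT1G75390) it went from 1.0 ± 0.474 to 1.93 ± 0.665 CPM (0.85 ± 0.41, adjusted p = 0.322). The 95% intervals of these log2 fold changes were -1.0 to 0.59 for bZIP11 and -0.10 to 1.80 for bZIP44, so neither was shown to be lower. Since bZIP2 goes against its label, the lines are called SnRK1-labelled and S1-labelled. The SnRK1 subunit KIN11 was also lower in the S1-labelled line, from 75.4 ± 9.48 to 43.5 ± 2.91 CPM (-0.80 ± 0.16, adjusted p = 0.0135), in 3 of 3 libraries, a comparison made after the values were seen. An insertion can leave reads from outside it, and cleaved transcripts can still be counted, so these levels do not measure protein or activity. The counts of the 5 S1 bZIPs equal those of the loci AT5G49448, AT2G18162, AT4G34588, AT1G75388 and AT3G62422 in every library, so each pair is 1 measurement.

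**Figure D2:**
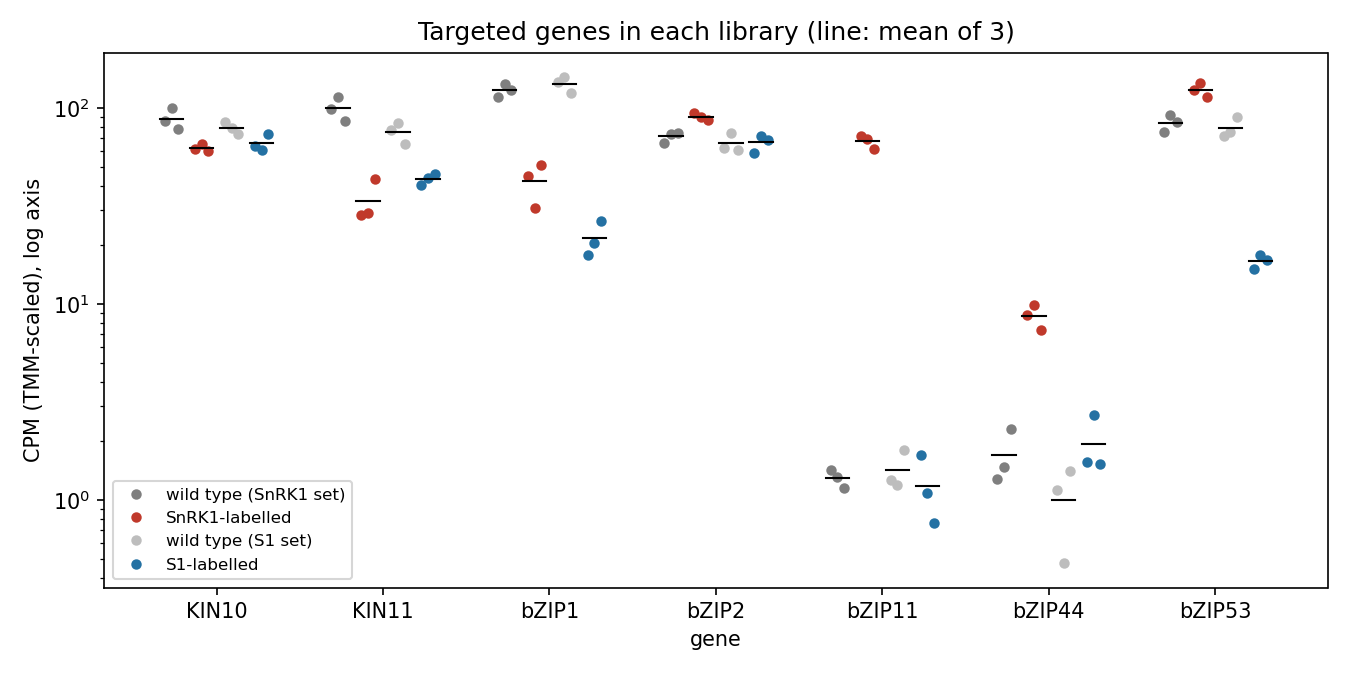
Log CPM of the 7 targeted genes in each of the 12 libraries, by group, with a black line at the mean of 3. KIN11 falls from 99.4 to 33.6 CPM in the SnRK1-labelled line, bZIP1 from 132 to 21.6 and bZIP53 from 78.9 to 16.5 in the S1-labelled line, and bZIP2 stays at 66.1 and 66.7.

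Against its own wild type, the SnRK1-labelled line held far more transcript of immune and defence genes, and less of genes of photosynthesis, branched-chain amino acid breakdown and the dark response. PAD3 (AT3G26830), the last enzyme of camalexin synthesis, rose from 1.1 ± 0.563 to 849 ± 198 CPM, and ICS1 (AT1G74710), which makes the precursor of salicylic acid, from 10.3 ± 1.66 to 223 ± 36.6 CPM. IVD (AT3G45300), an enzyme of leucine breakdown, fell from 893 ± 33.6 to 173 ± 58.0 CPM, and RCA (AT2G39730), the Rubisco activase, from 6112 ± 1483 to 1129.7 ± 439.7 CPM. ASN1 (AT3G47340), the dark-induced asparagine synthetase, fell from 8970.3 ± 1253 to 1208 ± 533 CPM (log2 fold change -2.89 ± 0.31, adjusted p = 3.47e-07). By edgeR's quasi-likelihood test, 6514 genes were higher and 6068 lower, 68.4% of those tested. Scaling by library totals alone moved the median of all genes from 0.04 to 0.64 and the counts to 10465 higher and 2938 lower (78.1% higher against 51.8%). Scaling on the 5000 most expressed genes moved the median to 0.40 and the counts to 8777 and 4035 (68.5% higher). Of the 126 genes named for this line by the fixed rule and called, 126 stayed called without each library in turn. The rule favours this outcome, since it picks genes with large or clear changes in these same libraries. Of all genes called in this line, at least 90.9% kept their call without any 1 of its 6 libraries.

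Genes of amino acid breakdown were mostly lower. Of 20 tested genes of branched-chain amino acid breakdown 16 fell and 2 rose (17 and 2 adjusted over the list alone; median log2 fold change -1.83, camera adjusted p = 7.07e-05, adjusted p = 0.331 with an estimated correlation). BCE1A1 (AT1G21400), a subunit of the branched-chain keto acid dehydrogenase, fell from 1311 ± 28.5 to 279 ± 81.4 CPM (log2 fold change -2.23 ± 0.20), while LPD2 (AT3G17240), a dihydrolipoamide dehydrogenase, rose from 49.9 ± 6.37 to 188 ± 39.5 CPM (1.91 ± 0.16). Of 21 genes that break down other amino acids 13 fell and 4 rose (median log2 fold change -0.78, camera adjusted p = 0.00102, adjusted p = 0.331 with an estimated correlation). The tyrosine aminotransferase gene TAT7 (AT5G53970) had a log2 fold change of -2.61 ± 0.19 (adjusted p = 3.90e-09). HPD (AT1G06570), the next enzyme of that pathway, fell from 1672 ± 119.6 to 261 ± 68.0 CPM (log2 fold change -2.68 ± 0.21, adjusted p = 9.10e-09). HGO (AT5G54080), which follows them, fell from 1770.0 ± 179.8 to 177 ± 43.5 CPM, but 27.4% of its exons are overlapped by a gene on the opposite strand, so its value is uncertain. Of 18 dark-induced and SnRK1 marker genes 15 fell and 2 rose (median log2 fold change -2.1, camera adjusted p = 9.77e-06, adjusted p = 0.331 with an estimated correlation). DRM1 (AT1G28330) and DRM2 (AT2G33830), dormancy-associated genes, fell by 2.14 and 2.69 on the log2 scale, and DIN11 (AT3G49620) rose from 11.4 ± 5.97 to 369 ± 194 CPM (log2 fold change 5.13 ± 0.44, adjusted p = 3.16e-08).

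Nuclear genes of the photosynthetic apparatus fell together, and those of cytosolic ribosomes rose. Of 34 genes of light harvesting and photosystems 33 fell (median log2 fold change -2.14, camera adjusted p = 1.61e-13, adjusted p = 0.331 with an estimated correlation). The antenna protein gene LHCB4.1 (AT5G01530) fell from 5369 ± 577 to 1030.2 ± 311 CPM (log2 fold change -2.38 ± 0.24, adjusted p = 1.57e-07). The photosystem I subunit gene PSAE1 (AT4G28750) fell from 1609 ± 161 to 404 ± 112 CPM (log2 fold change -2.00 ± 0.20, adjusted p = 2.17e-07). All 5 genes of Rubisco small subunits and activase fell (median log2 fold change -2.20, camera adjusted p = 0.00212, adjusted p = 0.331 with an estimated correlation). RBCS1A (AT1G67090) fell from 10683 ± 1676 to 2027 ± 783 CPM (-2.40 ± 0.30), with 1.5% of its exons in stretches identical to another gene. Of 38 cytosolic ribosomal protein genes 29 rose and 1 fell (30 and 1 adjusted over the list alone; median log2 fold change 0.62, camera adjusted p = 0.00102, adjusted p = 0.456 with an estimated correlation). RPS6A (AT4G31700) rose from 55.5 ± 5.61 to 172 ± 12.4 CPM (log2 fold change 1.63 ± 0.15, adjusted p = 4.99e-08). RPL18B (AT3G05590) rose from 73.3 ± 3.80 to 168 ± 13.8 CPM (log2 fold change 1.19 ± 0.12, adjusted p = 1.07e-07).

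Defence genes were among those with the largest changes. Of 17 genes of salicylic acid and the immune response 17 rose (median log2 fold change 6.67, camera adjusted p = 2.05e-23, adjusted p = 0.0874 with an estimated correlation). The median was 6.30 with 3 members at the bound set by 0 counts in the wild type. PBS3 (AT5G13320), which acts after ICS1 in salicylic acid synthesis, rose from 0.487 ± 0.186 to 237 ± 42.3 CPM (log2 fold change 8.78 ± 0.30, adjusted p = 1.06e-12). PR1 (AT2G14610), the classic marker of the salicylic acid response, had 0 counts in the 3 wild-type libraries and 185 ± 26.9 CPM in the line, at least 1090.5-fold higher against a floor of 3 counts over the group. On the same floor the immune regulator FMO1 (AT1G19250) was at least 461-fold and the peptide gene PNP-A (AT2G18660) at least 693-fold higher. Of 19 jasmonate genes 15 rose and 1 fell (median log2 fold change 3.10, camera adjusted p = 6.31e-05, adjusted p = 0.331 with an estimated correlation). Among them were the biosynthesis genes AOC3 (AT3G25780, 7.12 ± 0.39, adjusted p = 1.3e-10) and OPR3 (AT2G06050, 3.74 ± 0.22, adjusted p = 4.23e-10). Of 13 genes of glucosinolate synthesis 11 rose and 1 fell (median log2 fold change 2.94, camera adjusted p = 0.000298, adjusted p = 0.331 with an estimated correlation), with CYP79B2 (AT4G39950), the first enzyme from tryptophan, at 6.47 ± 0.35.

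Of 14 genes of senescence and chlorophyll breakdown 10 rose and 2 fell (median log2 fold change 1.25, camera adjusted p = 0.000735, adjusted p = 0.331 with an estimated correlation). SAG13 (AT2G29350) rose from 1.1 ± 0.563 to 142 ± 36.2 CPM (log2 fold change 7.15 ± 0.32, adjusted p = 1.17e-11). Of 6 genes of alternative respiration 5 rose and 1 fell (median log2 fold change 4.35, camera adjusted p = 1.17e-06, adjusted p = 0.0556 with an estimated correlation). The alternative oxidases AOX1A (AT3G22370) and AOX1D (AT1G32350) rose from 17.2 ± 1.85 to 243 ± 20.6 CPM and from 0.718 ± 0.879 to 242 ± 38.0 CPM. All 6 heat shock protein genes tested rose (median log2 fold change 3.79, camera adjusted p = 0.0147, adjusted p = 0.398 with an estimated correlation). HSP90.1 (AT5G52640) rose from 3.88 ± 0.877 to 87.8 ± 27.2 CPM (log2 fold change 4.45 ± 0.27, adjusted p = 4.82e-10). Of 19 circadian clock genes 10 fell and 4 rose (median log2 fold change -0.95, camera adjusted p = 0.00100, adjusted p = 0.331 with an estimated correlation). The morning genes CCA1 (AT2G46830, -1.80 ± 0.13, adjusted p = 3.96e-09) and RVE1 (AT5G17300, -3.08 ± 0.20, adjusted p = 1.21e-09) were lower.

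Sugar signalling and nitrogen genes moved in both directions. Of 18 trehalose metabolism genes 9 rose and 7 fell (median log2 fold change 0.48, camera adjusted p = 0.0362, adjusted p = 0.331 with an estimated correlation). That call was lost without replicate 1 or 3 of the wild type (adjusted p = 0.0502 and 0.0559) or replicate 3 of the line (adjusted p = 0.115). It was lost also by library totals (adjusted p = 0.124), without a filter on low counts (0.220), under the stricter filter (0.0583), without overlapping genes (0.327) and on the 5000 most expressed genes (0.0935). Its adjusted p over 23 settings ran from 0.00695 to 0.421, the highest under limma-voom. The trehalose phosphatase gene TPPJ (AT5G65140) rose from 0.439 ± 0.760 to 95.2 ± 10.2 CPM (log2 fold change 7.63 ± 0.41, adjusted p = 1.07e-10), and TPPD (AT1G35910) was at least 799-fold higher. Of 10 genes of nitrate and ammonium assimilation 5 rose and 2 fell (median log2 fold change 0.33, camera adjusted p = 0.302), with nitrite reductase NIR1 (AT2G15620, 2.70 ± 0.18, adjusted p = 1.67e-09) higher and ASN1 lower. Of 20 starch breakdown genes 8 rose and 5 fell (8 and 4 adjusted over the list alone; median log2 fold change 0.30, camera adjusted p = 0.745). The glucan phosphatase gene SEX4 (AT3G52180, 2.62 ± 0.21, adjusted p = 1.24e-08) was higher and BAM4 (AT5G55700, -2.03 ± 0.17, adjusted p = 1.96e-08) lower.

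Within the kinase complex itself 3 of 6 subunit genes fell (median log2 fold change -0.38, camera adjusted p = 0.123, median 0.22 by library totals). Besides the catalytic subunits, the beta subunit gene KINB1 (AT5G21170) fell from 631 ± 86.0 to 135 ± 46.9 CPM (log2 fold change -2.22 ± 0.21, adjusted p = 7.47e-08). Of 9 genes of the C and S1 bZIP groups 6 rose and 2 fell (median log2 fold change 0.34, camera adjusted p = 0.259). The gene bZIP11 rose from 1.3 ± 0.132 to 68.0 ± 5.44 CPM (log2 fold change 5.66 ± 0.19, adjusted p = 1.06e-12). In contrast, bZIP1 fell from 123 ± 9.51 to 42.4 ± 10.3 CPM (log2 fold change -1.55 ± 0.17, adjusted p = 3.95e-07), as did bZIP63 (AT5G28770), from 109 ± 4.19 to 36.5 ± 8.92 CPM (log2 fold change -1.59 ± 0.15, adjusted p = 9.48e-08). Of 39 autophagy genes 15 fell and 8 rose (median log2 fold change -0.25, camera adjusted p = 0.160, median 0.35 by library totals and 0.11 on the 5000 most expressed genes). ATG8F (AT4G16520) fell from 294 ± 11.6 to 111 ± 26.8 CPM. Of 22 genes of fatty acid beta-oxidation and the glyoxylate cycle 9 fell and 5 rose (median log2 fold change -0.14, camera adjusted p = 0.275, median 0.46 and 0.22 under those scalings). ACX4 (AT3G51840) fell from 792 ± 44.7 to 213 ± 51.7 CPM and LACS7 (AT5G27600) rose from 22.7 ± 1.92 to 72.0 ± 10.7 CPM.

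Of 23 abscisic acid and drought or cold genes 13 rose and 6 fell (median log2 fold change 0.69, camera adjusted p = 0.347). NCED3 (AT3G14440), the key enzyme of abscisic acid synthesis, was at 3.14 ± 0.25 and HB12 (AT3G61890) at -2.32 ± 0.17. Of 8 anthocyanin and flavonoid genes 3 rose and 2 fell (median log2 fold change 0.25, camera adjusted p = 0.785). The cell division and root marker lists, which check tissue make-up, were not called by camera, which does not exclude a changed tissue make-up. Of 8 cell division genes 3 rose (median log2 fold change 0.55, camera adjusted p = 0.199), with TSO2 (AT3G27060) from 6.14 ± 0.398 to 51.0 ± 13.6 CPM. Of 6 root markers 4 fell and 1 rose (median log2 fold change -1.89, camera adjusted p = 0.356, mean -0.03). The endodermis gene CASP2 (AT3G11550) fell from 6.5 ± 1.05 to 0.292 ± 0.402 CPM, and the nitrate transporter gene NRT2.1 (AT1G08090) was at least 88.7-fold higher. Of the flower markers only PISTILLATA was tested, at 4.17 ± 3.40 CPM in the wild type and 0.277 ± 0.195 in the line, and no seed storage gene had enough counts. For the lists of this line not given with a second count, the numbers adjusted over the list alone were the same.

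Of the genes with the lowest fold changes, RABA5E (AT1G05810), a Rab GTPase, fell from 32.2 ± 2.88 to 0.266 ± 0.113 CPM (log2 fold change -6.80 ± 0.24, adjusted p = 1.06e-12). GASA1 (AT1G75750), homologous to a gibberellin-regulated gene, fell from 760.4 ± 259 to 25.4 ± 12.3 CPM (log2 fold change -4.92 ± 0.34, adjusted p = 2.32e-09). FBA5 (AT4G26530), an aldolase, fell from 142 ± 31.8 to 5.74 ± 3.42 CPM (log2 fold change -4.67 ± 0.34, adjusted p = 4.51e-09). Among those with the highest, CYP71A13 (AT2G30770) of camalexin synthesis had 2 counts in the wild type, a ratio of 5185 (95% counting interval 1435 to 42821), with 22% of its exons overlapped from the opposite strand. By camera with its preset correlation, 14 of 24 lists differed from other genes. With an estimated correlation none did, and fry, which does not compare a list with other genes, called 23.

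**Figure D3:**
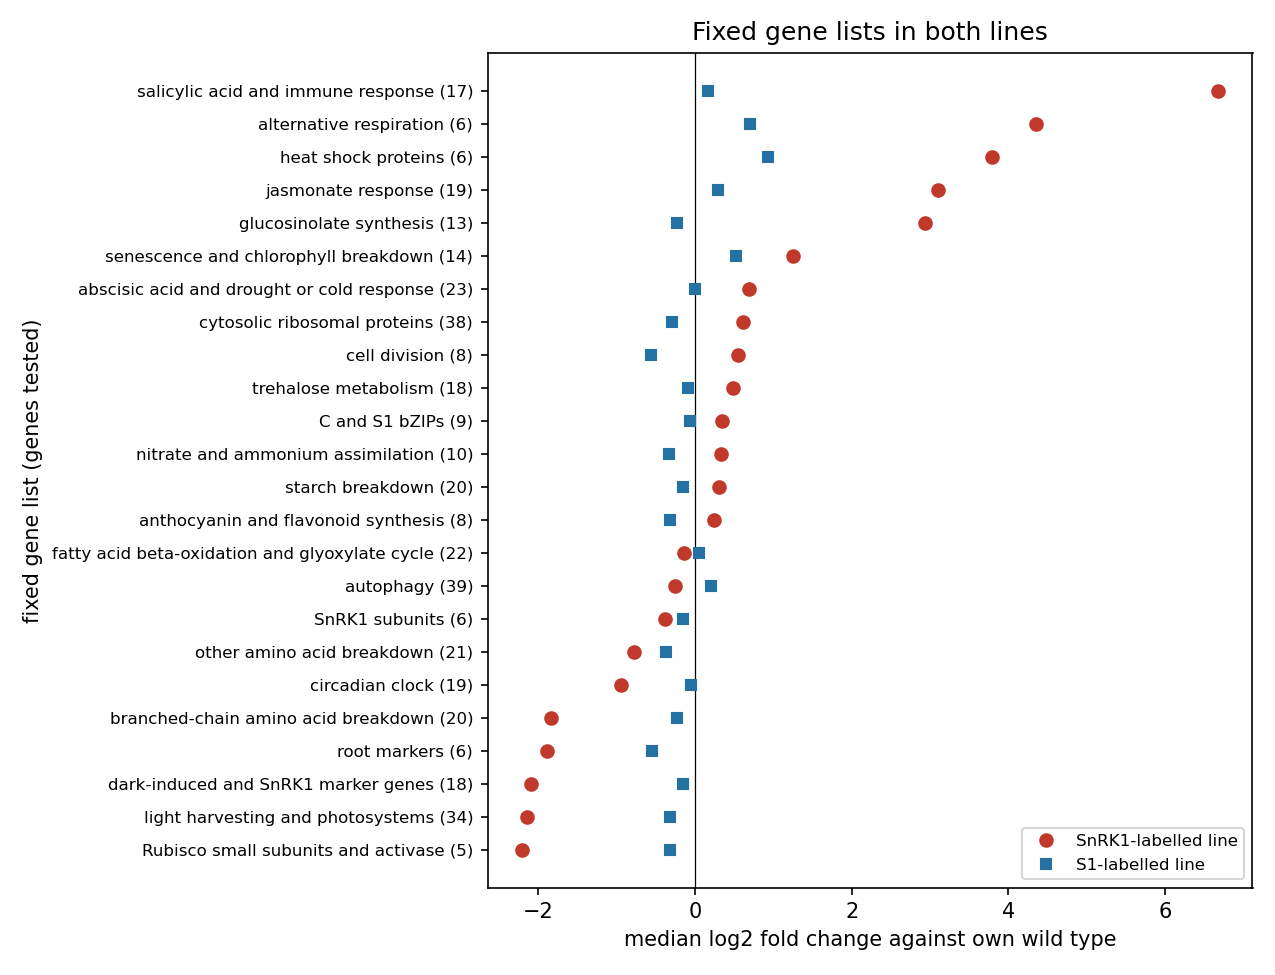
Median log2 fold change of each of the 24 tested gene lists in the SnRK1-labelled and the S1-labelled line, each against its own wild type. The immune list lies at 6.67 and 0.16, light harvesting and photosystems at -2.14 and -0.32, and branched-chain amino acid breakdown at -1.83 and -0.23.

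The S1-labelled line, with 1 d of Est rather than 6 d, differed from its wild type in far fewer genes. A gene of proline breakdown was among those that fell. ProDH1 (AT3G30775), proline dehydrogenase, fell from 3873 ± 425 to 1249 ± 99.9 CPM (log2 fold change -1.63 ± 0.22, adjusted p = 0.000810). GDPD2 (AT5G41080), a phosphodiesterase, fell from 426 ± 33.4 to 132 ± 16.6 CPM (log2 fold change -1.69 ± 0.25, adjusted p = 0.00179). MIOX4 (AT4G26260), an inositol oxygenase, fell from 6.62 ± 4.5 to 0.726 ± 0.116 CPM (log2 fold change -3.13 ± 0.49, adjusted p = 0.00273). Apart from the targeted genes these were among the lowest fold changes. The sucrose transporter gene SUC7 (AT1G66570), which shares stretches with SUC8, rose from 0.692 ± 0.606 to 8.34 ± 1.58 CPM (log2 fold change 3.49 ± 0.45, adjusted p = 0.000753). The lipase gene MPL1 (AT5G14180) rose from 5.64 ± 4.13 to 43.3 ± 4.21 CPM (log2 fold change 2.85 ± 0.43, adjusted p = 0.00210). The receptor-like protein gene RLP22 (AT2G32660) rose from 0.734 ± 0.345 to 5.49 ± 0.847 CPM (log2 fold change 2.78 ± 0.45, adjusted p = 0.00341). By edgeR, 299 genes were higher and 175 lower, against 2992 at an unadjusted p under 0.05. With only the groups compared in the fit these were 578 and 451, and with a replicate block 98 were lower. Library totals gave 558 higher and 102 lower (84.5% higher against 63.1%), with the median of all genes at 0.11.

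These counts changed when single libraries were left out, which also lowers the number of replicates. Without replicate 2 or 3 of the S1 wild type they were 91 higher and 49 lower, or 108 and 61. Without replicate 2 of the S1-labelled line they were 108 and 39, without its replicate 1 190 higher, and without its replicate 3 63 lower. Libraries of the SnRK1 experiment, which share the fit with its filter, scaling and spread, mattered too. The counts were 504 and 362 without replicate 3 of the SnRK1-labelled line, and 113 lower without replicate 2 of its wild type. Of 42 named genes called in this line, 28 stayed called without each library in turn.

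Genes of amino acid breakdown leaned lower in this line. Of 21 genes breaking down other amino acids 2 fell and 1 rose (8 and 2 adjusted over the list alone; median log2 fold change -0.37, camera adjusted p = 3.58e-05, adjusted p = 0.320 with an estimated correlation). Besides ProDH1, HGO fell from 837 ± 86.4 to 329.8 ± 33.7 CPM (log2 fold change -1.34 ± 0.19, adjusted p = 0.00122), with the overlap given above. Of 20 branched-chain genes 2 fell and 1 rose (6 and 2 adjusted over the list alone; median log2 fold change -0.23, camera adjusted p = 0.0269, adjusted p = 0.503 with an estimated correlation). This list's call was lost without replicate 1 of the wild type (adjusted p = 0.104) or of the line (0.193), by limma-voom (0.0619) and with a replicate block (0.136; range over 24 other settings 9.42e-07 to 0.193). Of 18 dark-induced genes 2 fell and 1 rose (3 and 2 adjusted over the list alone; median log2 fold change -0.15, camera adjusted p = 0.0931). DIN9 (AT1G67070) fell from 17.9 ± 2.41 to 8.88 ± 1.49 CPM (log2 fold change -1.01 ± 0.18, adjusted p = 0.00607), a call lost on thinned counts (adjusted p = 0.0544; range over 26 other settings 0.000371 to 0.0544). DIN3 (AT3G06850), a subunit gene of the branched-chain keto acid dehydrogenase that both lists hold, fell from 429 ± 31.1 to 190.1 ± 28.4 CPM (log2 fold change -1.18 ± 0.25, adjusted p = 0.0189). Its call was lost without replicate 2 or 3 of the wild type (adjusted p = 0.0668 and 0.0814) or replicate 1 or 2 of the line (0.0767 and 0.109; range over 26 other settings 4.95e-05 to 0.109).

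Of 38 cytosolic ribosomal protein genes 1 fell (6 adjusted over the list alone; median log2 fold change -0.29, camera adjusted p = 9.88e-10, adjusted p = 0.320 with an estimated correlation). RPL27AC (AT1G70600) fell from 74.2 ± 13.9 to 49.5 ± 5.81 CPM (log2 fold change -0.58 ± 0.14, adjusted p = 0.0379). This call was lost without replicate 2 or 3 of the SnRK1 wild type (adjusted p = 0.0580 and 0.0516) or replicate 1 or 3 of the S1 wild type (0.0614 and 0.186). It was lost also without replicate 2 or 3 of the S1-labelled line (0.202 and 0.135), and was weakest in a setting not named here (range over 26 other settings 0.0137 to 0.308). The photosystem list had a lower median (median log2 fold change -0.32, camera adjusted p = 1.48e-05, adjusted p = 0.503 with an estimated correlation), as did Rubisco (median log2 fold change -0.32, camera adjusted p = 0.103). Of 14 senescence genes 1 rose (7 higher and 1 lower adjusted over the list alone; median log2 fold change 0.53, camera adjusted p = 0.000628, adjusted p = 0.320 with an estimated correlation). SGR1 (AT4G22920), which starts chlorophyll breakdown, was at 0.57 ± 0.16 (adjusted p = 0.0707). Of 19 jasmonate genes 1 rose (3 adjusted over the list alone; median log2 fold change 0.29, camera adjusted p = 0.00168, adjusted p = 0.503 with an estimated correlation). LOX2 (AT3G45140) rose from 16.1 ± 10.4 to 94.0 ± 61.4 CPM (log2 fold change 2.49 ± 0.60, adjusted p = 0.0357). The LOX2 call was lost without replicate 2 or 3 of the wild type (adjusted p = 0.153 and 0.131) or replicate 1 or 2 of the line (0.147 and 0.0607; range over 26 other settings 0.00133 to 0.153). Autophagy genes had a higher median (median log2 fold change 0.21, camera adjusted p = 0.000240, adjusted p = 0.0552 with an estimated correlation). That call was lost against all 6 wild-type libraries (adjusted p = 0.0885; range over 24 other settings 1.45e-05 to 0.0885). Against the same S1 wild type, the SnRK1 wild type had similar medians for ribosomal proteins (-0.32), autophagy (0.23) and cell division (-0.63, here -0.55). For these lists a trait of the S1 wild type cannot be told apart from an effect of the line. Medians of both amino acid breakdown lists, photosystems, senescence, jasmonate, immune response and bZIPs had opposite signs in the 2 comparisons.

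Of 6 alternative respiration genes 1 rose (3 higher and 1 lower adjusted over the list alone; median log2 fold change 0.70, camera adjusted p = 0.0122, adjusted p = 0.191 with an estimated correlation). The list lost its call by limma-voom (adjusted p = 0.0534) and with only the groups compared in the fit (0.150; range over 24 other settings 0.00308 to 0.150). AOX1A rose from 13.2 ± 3.26 to 23.7 ± 3.26 CPM (log2 fold change 0.81 ± 0.17, adjusted p = 0.0173). The AOX1A call was lost without replicate 2 or 3 of the wild type (adjusted p = 0.0941 and 0.0944) or of the line (0.0811 and 0.0685). It was lost also with a replicate block (adjusted p = 0.0593) and against all 6 wild-type libraries (0.0525; range over 26 other settings 0.00166 to 0.0944). The immune list had a median of 0.16 (camera adjusted p = 0.0190, adjusted p = 0.503 with an estimated correlation). Its call was lost without replicate 2 of the wild type (adjusted p = 0.172) or replicate 1 or 2 of the line (0.0813 and 0.131), by library totals (0.0664), by limma-voom (0.0877) and with only the groups compared in the fit (0.136; range over 24 other settings 2.35e-05 to 0.172). The cell division list (median log2 fold change -0.55, camera adjusted p = 0.0190, adjusted p = 0.503 with an estimated correlation) lost its call without replicate 3 of the wild type (adjusted p = 0.158). It lost it also by limma-voom (0.0519), under the stricter filter (0.0933) and against all 6 wild-type libraries (0.637; range over 24 other settings 0.00407 to 0.637). Of 9 C and S1 bZIPs the targeted bZIP1 and bZIP53 fell (median log2 fold change -0.06, camera adjusted p = 5.50e-06, adjusted p = 0.0432 with an estimated correlation), and this list rests on them. Its call was lost by limma-voom (adjusted p = 0.0800), with a replicate block (0.136) and without overlapping genes (0.440).

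The other lists were not called by camera. Their medians were -0.16 for SnRK1 subunits, of which 1 fell (camera adjusted p = 0.0931), and -0.09 for trehalose metabolism (0.03 by library totals), of which 1 rose and 1 fell (adjusted p = 0.0728). Beta-oxidation was at 0.05 (adjusted p = 0.141, 5 higher and 3 lower adjusted over the list alone) and starch breakdown at -0.15 (adjusted p = 0.252), with 2 genes lower. The abscisic acid list was at -6.42e-05 (0.12 by library totals, adjusted p = 0.544), with 1 gene lower, and the clock at -0.05 (0.07 by library totals, adjusted p = 0.325). Heat shock proteins were at 0.93 (0.0728), anthocyanin synthesis at -0.32 (0.0970), glucosinolate synthesis at -0.22 (0.359), nitrate assimilation at -0.33 (0.0538) and root markers at -0.54 (0.329), each with its camera adjusted p. In 12 lists edgeR called 0 of the 187 members tested, against 43 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma-voom. The 12 were autophagy, beta-oxidation, photosystems, Rubisco, immune response, clock, heat shock, anthocyanin, glucosinolate, nitrate, cell division and root markers. Of 11 lists called, 1 kept its call with an estimated correlation, the bZIPs, and fry called 4.

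The series asks for genes under the control of both factors, so calls shared by the 2 lines, which had no control library in common, were counted. Leaving aside bZIP1 and the locus that shares its counts, genes with the strongest shared calls included SHM7 (AT1G36370), a serine hydroxymethyltransferase, and MAMI (AT5G54110), a membrane protein gene. They also included the efflux carrier gene AT2G04050, the auxin carrier gene PIN7 (AT1G23080), AT3G45730 and the sulfate reduction gene APR3 (AT4G21990). SHM7 rose by log2 fold changes of 1.33 ± 0.12 in the SnRK1-labelled and 1.12 ± 0.12 in the S1-labelled line, AT2G04050 of 8.98 ± 0.24 and 2.12 ± 0.25, and APR3 of 3.37 ± 0.21 and 1.54 ± 0.20. MAMI was at -1.31 ± 0.12 and -1.09 ± 0.12, PIN7 at -0.94 ± 0.12 and -0.92 ± 0.12, and AT3G45730 at -1.74 ± 0.12 and -1.0 ± 0.13. Among genes called in opposite directions, PAP85 (AT3G22640), a seed-type storage protein gene, was at -4.5 ± 0.36 and 1.84 ± 0.21, and the sugar alcohol transporter PMT6 (AT4G36670) at -1.34 ± 0.16 and 1.02 ± 0.15.

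Of 474 genes called in the S1-labelled line, 360 were also called in the SnRK1-labelled line, 261 of them (72.5%) in the same direction. The 168 genes higher in both compared with 105.9 for independent lists (odds ratio 2.37, Fisher's exact test, two-sided, adjusted p = 7.25e-13). The 93 lower in both compared with 57.7 (odds ratio 2.32, adjusted p = 5.34e-08). Genes higher in the SnRK1-labelled and lower in the S1-labelled line numbered 46 against 62.0 (odds ratio 0.648, adjusted p = 0.0109), and the reverse 53 against 98.7 (odds ratio 0.432, adjusted p = 7.79e-09). Genes are not independent of each other, so these p-values describe the lists. By the test of the difference, 139 of the 261 changed more in the SnRK1-labelled line, 4 more in the S1-labelled line, and for 118 it did not pass the threshold. The 261 became 526 without replicate 3 of the SnRK1-labelled line, 87 or 110 without replicate 2 or 3 of the S1 wild type, and 140 or 92 without replicate 1 or 2 of the S1-labelled line. The 99 opposite genes became 156 without replicate 3 of the SnRK1-labelled line and 64 without replicate 2 of its wild type. They became 27 or 30 without replicate 2 or 3 of the S1 wild type, and 25 or 40 without replicate 2 or 3 of the S1-labelled line.

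**Figure D4:**
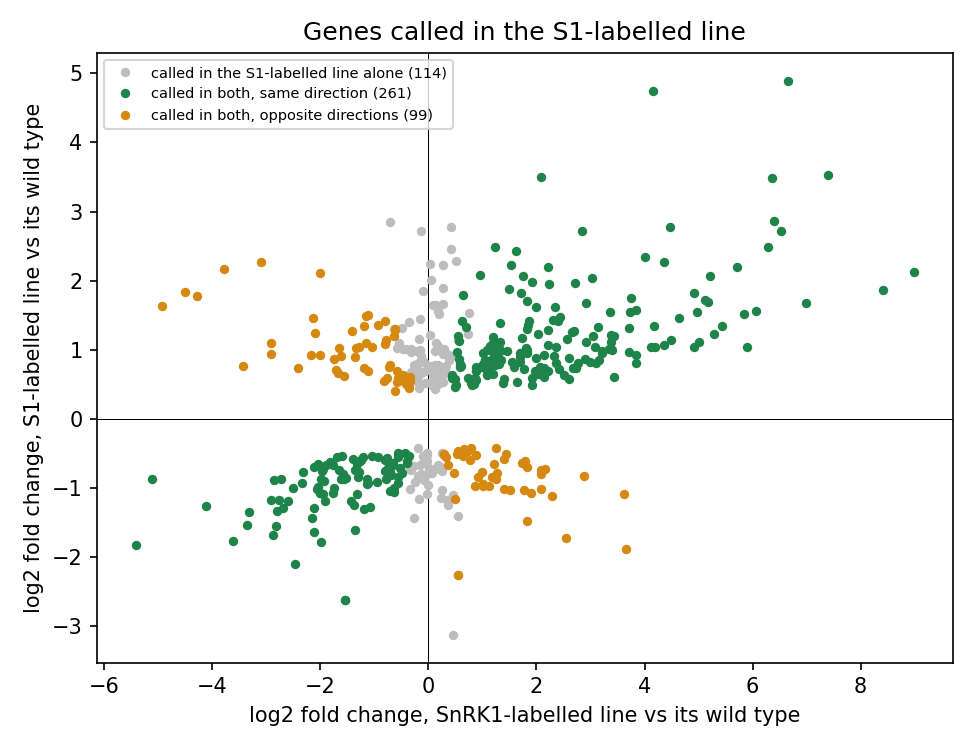
Log2 fold change in the SnRK1-labelled line (x axis) against that in the S1-labelled line (y axis) for the 474 genes called in the S1-labelled line, 1 point per gene. Of these, 261 were called in the same direction in both lines, 99 in opposite directions and 114 in the S1-labelled line alone.

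The test of the difference between the 2 responses asked which genes the lines moved unequally, with positive values for genes higher in the SnRK1-labelled response. The SnRK1-labelled line and its wild type had 6 d of Est, the S1-labelled line and its wild type 1 d. Line and days on Est therefore cannot be separated in this difference. Of 6 alternative respiration genes 4 were called above 0 and 1 below (median log2 fold change 3.30, camera adjusted p = 0.00456, adjusted p = 0.339 with an estimated correlation), a list call lost with a replicate block (adjusted p = 0.0782). ICS1 differed by 4.60 ± 0.25 (adjusted p = 2.59e-09), AOX1A by 3.03 ± 0.23 (adjusted p = 6.33e-08) and NIR1 by 3.09 ± 0.25 (adjusted p = 1.21e-07) on the log2 scale. The gene bZIP11 differed by 5.87 ± 0.46 and bZIP53 by 2.81 ± 0.18. By its label the S1-labelled line is a knockout of bZIP53. That gene was at -2.26 there and at 0.56 in the SnRK1-labelled line, so its difference rests mostly on the targeted fall. The lowest differences were RABA5E, -6.62 ± 0.29 (adjusted p = 1.20e-09), GASA1, -6.56 ± 0.44 (adjusted p = 1.81e-08), and PAP85, -6.33 ± 0.41 (adjusted p = 1.11e-08). The highest, TPPD, PNP-A, BAM5, AT4G03450 and PUB54, rest on groups at or near 0 counts and are given no fold. The calls of TPPD and PUB54 were lost without replicate 1 of the S1 wild type and that of BAM5 without its replicate 3 (adjusted p = 1).

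By edgeR, 5002 of 18388 differences were called above and 5013 below 0. Scaling by totals gave 7678 and 2601 (74.7% above against 49.9%, median of all genes 0.51) and on the 5000 most expressed genes 6951 and 3210 (68.4%, median 0.38). Called above 0 were 15 of 17 immune genes, 14 of 19 jasmonate genes (1 below), 11 of 13 glucosinolate genes and 30 of 38 ribosomal protein genes. Called below 0 were 33 of 34 photosystem genes, 15 of 18 dark-induced genes (2 above), 16 of 20 branched-chain genes (2 above; 17 below adjusted over the list alone) and 10 of 19 clock genes (3 above). By camera 15 of 24 lists were called, with an estimated correlation none, and fry 22. With a replicate block camera called 11, and by library totals 14. All called lists had an estimated-correlation adjusted p of at least 0.339. The bZIP call (camera adjusted p = 0.0399, adjusted p = 0.339 with an estimated correlation) was lost without replicate 1 or 3 of the SnRK1-labelled line (adjusted p = 0.0587 and 0.0544), replicate 1 of the S1 wild type (0.0522) or replicate 1 of the S1-labelled line (0.0559; range over 22 other settings 0.0283 to 0.717). It was lost also by limma-voom (0.0646), with a replicate block (0.0782) and without overlapping genes (0.717). The bZIP list holds the targeted bZIP1 and bZIP53, whose fall in the S1-labelled line feeds this difference. The senescence call (camera adjusted p = 0.0312, adjusted p = 0.392 with an estimated correlation) was lost without replicate 1 or 2 of the SnRK1-labelled line (0.0526 and 0.0634) or replicate 2 of the S1 wild type (0.0556; range over 22 other settings 0.0116 to 0.125). It was lost also by limma-voom (0.0833), with a replicate block (0.125), without overlapping genes (0.124) and on thinned counts (0.0546). The root markers had a median of -1.48 but a mean of 0.46.

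The 2 wild types differed too, which gives the background between experiments. With 6 d rather than 1 d on Est, single genes of the cold and drought response were lower. In the order 1 d to 6 d, RD29A (AT5G52310) went from 40.4 ± 18 to 3.5 ± 0.799 CPM (log2 fold change -3.45 ± 0.36, adjusted p = 4.24e-05). KIN2 (AT5G15970), which is cold-induced and no kinase subunit, went from 129 ± 37.7 to 16.3 ± 6.32 CPM (log2 fold change -2.93 ± 0.28, adjusted p = 1.86e-05). COR15A (AT2G42540) went from 7.17 ± 2.86 to 0.762 ± 0.634 CPM (log2 fold change -3.10 ± 0.47, adjusted p = 0.000683). The nitrate reductase gene NIA2 (AT1G37130) went from 3674 ± 563 to 1328 ± 217 CPM (log2 fold change -1.47 ± 0.22, adjusted p = 0.000683), and the clock gene PRR5 (AT5G24470) from 71.6 ± 3.85 to 27.8 ± 5.95 CPM (log2 fold change -1.39 ± 0.15, adjusted p = 6.06e-05). Higher with 6 d were MLP329 (AT2G01530), from 5.56 ± 0.605 to 27.5 ± 3.62 CPM, and AT5G18840, a sugar-transporter family gene, from 4.83 ± 2.1 to 58.6 ± 13.8 CPM (log2 fold change 3.5 ± 0.31, adjusted p = 1.13e-05). By edgeR, 1135 genes were higher and 1092 lower with 6 d, or 724 and 1438 by library totals and 829 and 1557 on the 5000 most expressed genes (33.5% and 34.7% higher against 51.0%).

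Of 10 nitrate and ammonium assimilation genes 6 were lower with 6 d (median log2 fold change -0.68, camera adjusted p = 0.000133, adjusted p = 0.267 with an estimated correlation). Of 23 abscisic acid and cold genes 6 were lower and 1 higher (7 and 2 adjusted over the list alone; median log2 fold change -0.38, camera adjusted p = 0.000173, adjusted p = 0.175 with an estimated correlation). Of 38 ribosomal protein genes 15 were lower (20 lower and 2 higher adjusted over the list alone; median log2 fold change -0.32, camera adjusted p = 0.000133, adjusted p = 0.342 with an estimated correlation). Of 21 genes breaking down other amino acids 7 were higher (11 adjusted over the list alone; median log2 fold change 0.39, camera adjusted p = 1.34e-06, adjusted p = 0.267 with an estimated correlation). Of 20 branched-chain genes 6 were higher (7 adjusted over the list alone; median log2 fold change 0.33, camera adjusted p = 0.000837, adjusted p = 0.342 with an estimated correlation). AGT2 (AT4G39660), of the list of other amino acid breakdown, went from 98.1 ± 12.3 to 221 ± 15.9 CPM (1.17 ± 0.13, adjusted p = 7.76e-05). The autophagy list had a higher median (3 of 39 higher; median log2 fold change 0.23, camera adjusted p = 0.00308, adjusted p = 0.175 with an estimated correlation), as had beta-oxidation (2 of 22 higher, 3 adjusted over the list alone; median log2 fold change 0.22, camera adjusted p = 0.00692, adjusted p = 0.342 with an estimated correlation). Senescence, jasmonate and alternative respiration lists were not called, and their median, mean and test differed in sign.

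A further 7 lists were called here and lost their call without single libraries. Cell division (median log2 fold change -0.63, camera adjusted p = 0.0154, adjusted p = 0.342 with an estimated correlation) lost it without replicate 3 of the SnRK1 wild type (adjusted p = 0.0597) or of the S1 wild type (0.0816; range over 23 other settings 0.00365 to 0.0816). So did Rubisco (median log2 fold change -0.49, camera adjusted p = 0.0347, adjusted p = 0.397 with an estimated correlation, then 0.119 and 0.0988, range over 23 other settings 0.00389 to 0.119). Of its 5 genes edgeR called 0, against 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The clock (median log2 fold change -0.02, camera adjusted p = 0.0243, adjusted p = 0.342 with an estimated correlation) lost it without replicate 3 of the SnRK1 wild type (0.0597) or 2 of the S1 wild type (0.0594; range over 23 other settings 0.00939 to 0.0946), where its median was 0.06 and 0.08. Glucosinolates lost it (median log2 fold change -0.32, camera adjusted p = 0.0154, adjusted p = 0.425 with an estimated correlation) without replicate 2 of the SnRK1 wild type (0.0504; range over 23 other settings 0.00749 to 0.0504). Trehalose metabolism (median log2 fold change -0.28, camera adjusted p = 0.0367, adjusted p = 0.342 with an estimated correlation) lost it without replicate 1 or 3 of the SnRK1 wild type (0.0508 and 0.112) or 3 of the S1 wild type (0.117; range over 23 other settings 0.00928 to 0.117). Heat shock proteins (median log2 fold change 1.76, camera adjusted p = 0.0154, adjusted p = 0.342 with an estimated correlation) reached adjusted p = 0.165 without replicate 1 of the SnRK1 wild type, the highest (range over 23 other settings 0.00628 to 0.165). The others were replicate 2 of that group (0.0504), replicates 2 and 3 of the SnRK1-labelled line (0.0670 and 0.0551), replicates 1, 2 and 3 of the S1 wild type (0.0509, 0.117 and 0.0885) and replicate 2 of the S1-labelled line (0.0627). Root markers (median log2 fold change 0.42, camera adjusted p = 0.0234, adjusted p = 0.267 with an estimated correlation) kept their call only without replicate 3 of the SnRK1 wild type, replicate 2 of the SnRK1-labelled line or replicate 3 of the S1 wild type. Without the others their adjusted p was 0.0624 to 0.276 (range over 22 other settings 0.00136 to 0.586), and their median was -0.02 without replicate 1 of the S1 wild type. By limma-voom the calls of trehalose metabolism (adjusted p = 0.0586), the clock (0.0946) and heat shock proteins (0.110) were lost, and with a replicate block those of trehalose metabolism (0.0565) and the clock (0.0811). With only the groups compared in the fit, trehalose metabolism (0.0861) and cell division (0.0631) lost theirs. So did heat shock proteins (0.0793) and root markers (0.586) without a filter, the clock under the stricter one (0.0578), and trehalose metabolism (0.0750) and root markers (0.0888) on thinned counts.

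The counts between the wild types fell without single libraries to 753 higher (replicate 1 of the SnRK1 wild type), 622 higher and 589 lower (its replicate 2), and 646 and 617 (its replicate 3). Without replicate 2 or 3 of the S1 wild type they were 671 and 702, or 623 and 639. Of 60 named genes called, 44 stayed called without each library in turn. Days on Est and experiment cannot be separated in these libraries.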

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

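Apart from the test on gene length and GC content and the counts over other splits of the libraries, the tests in this part were chosen after the results they measure had been seen. The lines differed in their responses by a test of the difference itself: 5002 genes had a larger log2 fold change in the SnRK1-labelled line and 5013 a smaller one. Line and days on Est (6 d and 1 d) cannot be separated in this test. The median difference was 5.98 for the immune list, 3.30 for alternative respiration, 2.78 for glucosinolate synthesis, 2.18 for jasmonate, 1.31 for cell division, 0.91 for senescence, 0.90 for ribosomal proteins and 0.47 for the C and S1 bZIPs. It was -1.92 for dark-induced genes, -1.87 for Rubisco, -1.81 for photosystems, -1.30 for branched-chain amino acid breakdown, -1.13 for the clock, -0.58 for autophagy and -0.48 for other amino acid breakdown. These lists were called by camera with its preset correlation, and none with an estimated one. The bZIP list holds bZIP1 and bZIP53, knockout targets of the S1-labelled line, so part of its difference follows from the targeting. The medians depend on the scaling. The median difference of all genes was 0.03, but 0.51 by library totals and 0.38 on the 5000 most expressed genes. Such shifts are close in size to the smaller list medians, among them those of autophagy and other amino acid breakdown. The 99 genes called in opposite directions in the lines were also called in the test of the difference, which their selection by opposite signs in the same fit all but fixes, so this is no further evidence. Over 74 splits drawn, 1, the real one, gave 10015 genes and the highest other 9949. At an unadjusted p under 0.05 another split gave more, 10912 against 10904. The 8 splits that keep the real SnRK1 groups follow the SnRK1-labelled line's own response, so this count does not test the difference between the lines.

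The size of the SnRK1-labelled line's response was weighed first. Of its called genes 72.8% kept call and direction under every scaling tried, which argues against scaling as the whole cause, though scaling sets how calls divide by direction. Of 7213 genes with a 2-fold change 87.5% kept it once a trend on gene length and GC content was taken off, a trend that explained 1.00% of the variance. Without any 1 of the 6 libraries at least 90.9% of the called genes kept their call. The loss of SnRK1 as the source stays a hypothesis, which these checks do not test, and effects of the construct itself were not tested. Besides, 10 splits of 6 libraries are too few for a share under 0.05 (12582 genes in 1 of the 10 splits, the real one, with a highest other of 0 by edgeR and 908 at an unadjusted p under 0.05).

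The lean of the S1-labelled line's changes toward the direction of the SnRK1-labelled line was weighed next. The odds ratio of the overlap stayed at 2.04 or above in both directions under every scaling tried, which argues against scaling. Only the real split of 74 drawn gave 261 genes in the same direction (highest other 0 by edgeR; 1429 against 529 at an unadjusted p under 0.05), but mixed splits called 0 genes by edgeR in either line alone, so this says nothing about shared direction. A single library stays open, since without replicate 1 of the S1-labelled line the odds ratio for genes lower in both was 1.26. A partial loss of SnRK1 in the S1-labelled line could also give such a lean, and KIN11 was lower there. Along the SnRK1-labelled line's change, over 12582 genes, the S1-labelled libraries lay 0.0413 (standard error 0.0254) above their wild type (exact permutation test, two-sided, p = 0.3, with 0.1 the smallest possible), with 2 of 3 above every wild-type library. Both lines, unlike their wild types, carry an inducible knockdown. A partial loss of SnRK1, shared control by both factors and effects of the constructs therefore cannot be told apart.

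The difference between the wild types was weighed last. With every library thinned to the smallest total 1751 genes were still called, which argues against depth as the whole cause. The labels say that all plants were harvested together, which speaks against another harvest time, and the clock genes alone do not settle whether their phase differed: the 8 morning clock genes lay 0.26 (standard error 0.39) above the 7 evening ones in log2 fold change. Days on the inducer cannot be told apart from the experiment, since all 2227 called genes compare 6 d with 1 d. For these genes, and for the 474 called in the S1-labelled line, 10 splits are too few for a share under 0.05, with highest other counts of 0 by edgeR (1025 and 983 at an unadjusted p under 0.05, against 5085 and 2992 in the real splits).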

How the results depend on the processing

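The settings that left out overlapping genes, thinned the counts, used all 6 wild types or scaled on the 5000 most expressed genes were chosen after seeing the data. Library totals alone gave 10465 higher and 2938 lower genes in the SnRK1-labelled line, 558 and 102 in the S1-labelled line, 7678 and 2601 in the difference, 724 higher between the wild types, 454 called in the same direction in both lines, and KIN10 at 0.10. The 5000-gene scaling gave 4035 lower genes in the SnRK1-labelled line and 3210 in the difference. With only the groups compared in the fit the S1-labelled line had 578 higher and 451 lower genes, with 573 in the same and 198 in opposite directions. The labels do not pair libraries by number, and same-numbered ones did not correlate best throughout; a replicate block gave 98 lower genes in the S1-labelled line and 65 in opposite directions. Limma-voom called 6 lists in the S1-labelled line, and no filter gave 401 genes in the same direction. The cause was not tested. A 2-fold minimum gave, by its construction, 4253 and 3037, 149 and 59, 2902 lower in the difference, 241 and 343 between the wild types, and 117 same and 28 opposite. Without overlapping or identically counted genes the bZIP list reversed its camera direction in the S1-labelled line (adjusted p = 0.440) and in the difference (0.717). Its median went from -0.06 to 0.076 in the S1-labelled line. In the difference it went from 0.47 to 0.15, so its sign did not change there. The 5 S1 bZIPs, whose counts equal those of another locus, are left out in this setting.

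Leaving out each library in turn gave 5896 to 6753 higher and 5701 to 6293 lower genes in the SnRK1-labelled line, 91 to 504 and 39 to 362 in the S1-labelled line, 4472 to 4965 and 4662 to 5447 in the difference, and 622 to 1450 and 589 to 1409 between the wild types. Genes in the same direction ranged from 87 to 526 and in opposite directions from 25 to 156. Lists called ranged over 13 to 14, 10 to 14, 13 to 16 and 10 to 14. DESeq2 and the 2-fold minimum gave no list value, and the fit of only the groups compared none for the difference. Of the named genes' values under other settings 4688 kept direction and side of the threshold, 76 fell below it, 74 passed it and 1 reversed; for lists 991, 41, 17 and 2. Without single libraries these were 4362, 153 and 45 for genes and 1084, 43 and 25 for lists, with 0 reversed. Thinning every library to the smallest total left 221 higher and 140 lower genes in the S1-labelled line, against 299 and 175. On simulated counts 16.4% of 1.5-fold changes were called in the S1 comparison, where depth, replicate number and spread were not varied separately.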

Other observations

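All comparisons of gene families were chosen after seeing the data. In the SnRK1-labelled line 10 families held more higher genes than a random draw would give (adjusted p < 0.05), 7 of them named here. Of 49 NAC transcription factors 40 were higher, against 17.7 for a random draw, with a median log2 fold change of 2.07 (Fisher's exact test, one-sided, adjusted p = 2.07e-08). Of 44 WRKY factors 34 were higher (adjusted p = 3.90e-06), of 44 receptor-like proteins 33 (adjusted p = 1.47e-05) and of 31 cysteine-rich receptor-like kinases 25 (adjusted p = 3.31e-05). Of 15 multidrug resistance-associated proteins 14 were higher (adjusted p = 0.000349), of 49 TIR-NBS-LRR proteins 32 (adjusted p = 0.00137) and of 18 VQ motif proteins 14 (adjusted p = 0.0117).

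Of 99 RNA recognition motif proteins 50 were lower (adjusted p = 0.00655, median -0.38, but 0.23 by library totals and -0.02 on the 5000 most expressed genes), and of 178 RING/U-box proteins 79 (adjusted p = 0.0165, median 0.35 by library totals and 0.11 on the 5000 most expressed genes). In the S1-labelled line 12 of 117 cytochrome P450 genes were higher, against 1.93 for a random draw (adjusted p = 0.000147), and 6 of 44 WRKY factors (adjusted p = 0.0112). Of 36 pectin lyase-like proteins 4 were lower (adjusted p = 0.0373), 1 by library totals. All family tests were one-sided, for more called genes than a random draw. Genes are not independent, so these p-values, adjusted over 284 tests on 142 families in each comparison, describe the lists.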
